A study of Mus musculus with 4 samples.

How the data were processed

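Total RNA of B16F10 cells was measured on Affymetrix mouse genome array strips (GeneAtlas system, 3-prime in vitro transcription labelling with biotin, 1 sample per array), per the labels' protocols. The deposited values were log2 expression values, 1 per probe set and array. Per the submitters' processing notes, the tools were RMA, Affymetrix Expression Console and Transcriptome Analysis Console, with versions not given in the sources used here. RMA subtracts background, makes the distributions of the arrays alike and summarises the probes of a probe set, so a shift of most genes in 1 direction would be removed and weak signals are compressed. The distributions of the 4 arrays were close but not identical: minima lay between 2.22 and 2.25, maxima between 12.96 and 12.99, and the upper quartile was 6.26 on plumbagin 1 against 6.34 to 6.36 on the others, a gap near the size of the smaller list medians. Scanner images and probe-level intensities were not used here.

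The value table held 45141 probe sets, of which 104 were control probe sets. The platform's probe annotation, which can be out of date, listed 29449 probe sets, 28898 with 1 gene symbol and 551 with several. The other 15588 probe sets, control probe sets left aside, were unnamed here and were not tested. Symbols were updated through the Entrez gene number for the 28689 probe sets whose number was in a RefSeq gene table of assembly GRCm38.p6, used for names alone. No coordinates were used. Each of the 17097 genes was represented by the probe set with the highest mean over the 4 arrays; 7180 genes had more than 1. No filter on dim genes was applied in the main comparison.

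Groups were taken from the sample titles, 2 controls and 2 plumbagin samples. Differences were fitted on the log2 scale with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without covariates, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Before the data were examined, 25 pathway lists and 6 cell type marker lists were fixed from general knowledge; 619 of their 685 entries were measured, 14 of them through an older symbol. The 24 pathway lists and 5 marker lists with at least 4 measured members were tested with camera (two-sided, preset correlation of 0.01), adjusted over each family. The same lists were tested with camera using the correlation estimated from the residuals. That version has only the few residual degrees of freedom of 4 arrays, so a list can hardly pass. The lists were also tested with fry, which asks whether a list's genes move on balance in 1 direction and sets them against no other genes. Members of a list were also adjusted over the list alone.

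Genes named in the text were fixed by rule: in each direction the 12 genes with the smallest p, or those past the threshold where 12 passed, with both plumbagin arrays on the same side of both controls and a mean above the 95th percentile of the odorant receptor genes, which were assumed not to be transcribed here; unnamed loci were skipped. In each pathway list up to 4 members with the smallest p could be named. Hmox1, Srxn1, Cbr3, Ppp1r15a, Atf3, Tiparp, Cyp1a1, Cyp1b1, the genes named between the numbers and the melanin genes Tyr, Tyrp1, Dct, Pmel and Mitf lie outside this rule.

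Medians of lists within a replicate number were set against the medians of 10000 random lists of the same size, drawn from 40 bins of mean brightness; a median was taken to depart where it lay outside percentiles 2.5 to 97.5. This step and cyclic loess normalization between arrays were added after seeing the data. The alternatives fixed before were the mean of a gene's probe sets, every probe set on its own, 2 filters on dim genes, quantile normalization again, centring on array medians, eBayes with a trend or robust, the replicate number as a block, and leaving out each array in turn, where the lone array was assumed to vary like the other group.

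The code was tested on simulated data drawn from the spread of these arrays, with 17097 genes in 20 simulations. Genes moved by 3 on the log2 scale were called in 95.3% of cases. Of 2391 calls, 114 were genes that had not been moved, and a list moved as a whole was called in 20 of 20 simulations, with 1 other list called in all of them together. That list was moved by more than any list median found in the main comparison. The power of the list test at the sizes found here was therefore not simulated. The simulated genes varied independently and with no difference between replicate numbers, so these rates hold for that case alone. In the arrays, estimated correlations were 0.72 for G1/S genes, 0.45 for ATF4 targets, 0.13 for ribosome biogenesis and -0.04 for immediate early genes.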

Results

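Gene expression was measured on 4 arrays of B16F10 cells, a pigmented mouse melanoma line derived from the C57BL/6 strain. Cells of 2 samples were given MilliQ water (0 µM plumbagin, control 1 and control 2), and cells of 2 samples were given 2 µM plumbagin, a plant naphthoquinone, for 24 h (plumbagin 1 and plumbagin 2). The labels do not say whether the samples of a group were separate cultures, so p-values here measure the spread between these samples, which could be technical. Each array held 45141 probe sets, and 17097 named genes were compared. The median log2 value per array lay between 4.32 and 4.39, with upper quartiles between 6.26 and 6.36. Of the 17097 genes, 8637 (50.5%) had a mean above 5.05, the 95th percentile of 41 odorant receptor genes, which served as a background level. Precision was limited by the number of arrays, 2 per group.

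Plumbagin was compared with the control to ask which transcripts differed after 24 h at 2 µM. Ribosome biogenesis genes, targets of the stress transcription factor ATF4, immediate early genes, and genes of the G1/S transition and DNA replication fell as lists by camera, and no list was called higher. All 4 calls were lost with an estimated correlation between genes (adjusted p = 0.875 for each), and fry called 0 lists. Estimated correlations were high for G1/S genes (0.72) and ATF4 targets (0.45), which weakens their calls with the preset. For ribosome biogenesis (0.13) and immediate early genes the loss is not correlation alone, as that version of camera has little power on 4 arrays. Immediate early genes had an estimated correlation of -0.04, below the preset 0.01. Their unadjusted camera p still went from 0.00207 to 0.0761. The median differences were small: -0.20 for ribosome biogenesis (1.15-fold lower), -0.20 for ATF4 targets (1.15-fold lower), -0.20 for immediate early genes (1.15-fold lower) and -0.14 for G1/S and DNA replication (1.11-fold lower). No single gene passed an adjusted p of 0.05. The melanocyte pigmentation list and the NRF2 antioxidant list were not called in either direction.

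Ribosome biogenesis genes, which make and assemble ribosomal RNA and its nucleolar particles, were lower in 22 of 26 measured members. Camera, a limma test of a list against the other genes, gave an adjusted p of 5.35e-07 over 24 lists, and the adjusted p was 0.875 with an estimated correlation between genes in place of the preset 0.01. Polr1a, the largest subunit of RNA polymerase I, differed by -0.46 ± 0.09 (log2, SE, n = 2 per group). Nop16, a nucleolar protein, differed by -0.37 ± 0.08, Rrp1b by -0.27 ± 0.09, and Pprc1, a PGC-1-related coactivator, by -0.43 ± 0.17. Both plumbagin arrays lay below both control arrays in 14 of the 26 members, against 2597 of all 17097 genes; in the other lists that fell this held for 11 of 29 ATF4 targets, 6 of 24 immediate early genes and 6 of 34 G1/S genes. Chance gives 33.3% of genes apart when both directions are counted together, so less for the lower direction alone, which these counts give. The count over all genes was not matched on brightness, on which differences in the arrays with number 1 depended, as given below. The list's median was -0.30 between plumbagin 1 and control 1 and -0.10 between plumbagin 2 and control 2, and it was -0.11 without plumbagin 1 (adjusted p = 0.00698). No member passed over all genes tested, and 0 passed when adjusted over the list alone.

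Targets of ATF4, the transcription factor of the integrated stress response, were lower in 27 of 29 measured members (camera adjusted p = 1.82e-06, and adjusted p = 0.875 with an estimated correlation). Psph and Phgdh, enzymes of serine synthesis, differed by -0.30 ± 0.10 and -0.27 ± 0.13 (log2, SE), and the alanyl- and seryl-tRNA synthetases Aars and Sars by -0.27 ± 0.10 and -0.26 ± 0.11. Ppp1r15a, which directs dephosphorylation of eIF2α, and Atf3, a stress-induced transcription factor, had lower means of -0.94 ± 0.78 and -0.69 ± 0.38; both were chosen after their values were seen. Ppp1r15a differed by -1.56 between plumbagin 1 and control 1 but by -0.32 between plumbagin 2 and control 2, and its difference turned to 0.12 without plumbagin 1. The list's median was -0.36 in the arrays with number 1 and -0.08 in those with number 2. Between the controls it was -0.12, control 1 minus control 2, larger in size than the number 2 difference. Without plumbagin 1 it was -0.07 and the camera call was lost (adjusted p = 0.321), and without plumbagin 2 it was -0.36. Plumbagin 1 also stood apart in its hybridization spike-in controls, with a mean log2 value of 9.79 against 8.73 to 9.04 on the other arrays. No member passed over all genes or adjusted over the list alone (0 and 0).

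Immediate early genes, the rapidly induced transcription factors and feedback regulators of growth factor signalling, were lower in 17 of 24 measured members (camera adjusted p = 0.0124, and adjusted p = 0.875 with an estimated correlation). Dusp1, a MAP kinase phosphatase, differed by -0.41 ± 0.11 (log2, SE), Jun, an AP-1 subunit, by -0.61 ± 0.27, Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, by -0.27 ± 0.12, and Ier2 by -0.32 ± 0.15. The median was -0.19 in the arrays with number 1 and -0.16 in those with number 2, and it was -0.09 without plumbagin 1 (adjusted p = 0.0187). The call was lost without control 2 (median -0.08, adjusted p = 0.224), without plumbagin 2 (median -0.21, adjusted p = 0.0805) and with arrays centred on their medians (median -0.22, adjusted p = 0.0630). Again 0 members passed over all genes and 0 adjusted over the list alone.

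Genes of the G1/S transition and DNA replication were lower in 31 of 34 measured members (camera adjusted p = 0.0124, and adjusted p = 0.875 with an estimated correlation). Rfc4 and Rfc3, subunits of the clamp loader of replication, differed by -0.37 ± 0.13 and -0.33 ± 0.17 (log2, SE), Cdt1, a replication licensing factor, by -0.14 ± 0.08, and E2f8, an atypical E2F repressor, by -0.25 ± 0.14. No member passed over all genes or adjusted over the list alone (0 and 0). This list was also higher in control 1 than in control 2, by a median of 0.44, which exceeded its difference between the treatments. Its direction therefore depended on which arrays were used: the median was 0.10 without control 1 (adjusted p = 0.107) and 0.05 without plumbagin 2 (adjusted p = 0.582), against -0.42 without control 2 and -0.32 without plumbagin 1. The call was also lost with either filter on dim genes (adjusted p = 0.0995 and 0.103), with repeated quantile normalization (0.133) and with cyclic loess normalization (0.0538).

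Differences between plumbagin 1 and control 1 depended on brightness. Among genes with a mean log2 value between 7 and 8, near the median levels of the ribosome biogenesis list (7.91) and the G1/S list (7.97), the median of all genes was -0.17 in the arrays with number 1 and within 0.01 of 0 in those with number 2. Below 4 the number 1 median was 0.02, and above 10 it was -0.06. All 24 lists were therefore also set against 10000 random lists matched on brightness within each number, as a description of these arrays. In the arrays with number 2 the medians of ribosome biogenesis (-0.10), ATF4 targets (-0.08), immediate early genes (-0.16) and G1/S genes (-0.10) all lay at percentile 0. In the arrays with number 1 they lay at percentiles 0.02, 0, 0.52 and 1.74. Cholesterol synthesis genes, which camera did not call, departed upward in both numbers, with medians of 0.02 at percentile 98.0 in number 1 and 0.06 at percentile 98.8 in number 2. G2/M genes lay at percentile 98.6 in number 1 and 0 in number 2. After cyclic loess the number 1 percentiles of these lists, 96.6 and 95.5, were inside the central 95%. Loess also took replication-dependent histones inside in number 1 (1.61 to 2.92). It took hypoxia response genes (94.6 to 99.5) and ER chaperones (91.6 to 98.5) outside. Before loess, 8 lists lay outside the central 95% in number 1 and 9 in number 2, where 1.2 are expected for lists of unrelated genes. Lists also departed between the 2 untreated controls, so a departure does not need treatment. Taken as control 1 minus control 2, G1/S genes lay at percentile 100, pentose phosphate genes at 99.98, and ATF4 targets at 0.06. Immediate early genes lay at 0.99 (median -0.07), while ribosome biogenesis lay at 16.1, inside the central 95%. In the arrays with number 2, 22 of 26 ribosome biogenesis genes, 25 of 29 ATF4 targets, 20 of 24 immediate early genes and 29 of 34 G1/S genes were lower with plumbagin.

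**Figure D1:**
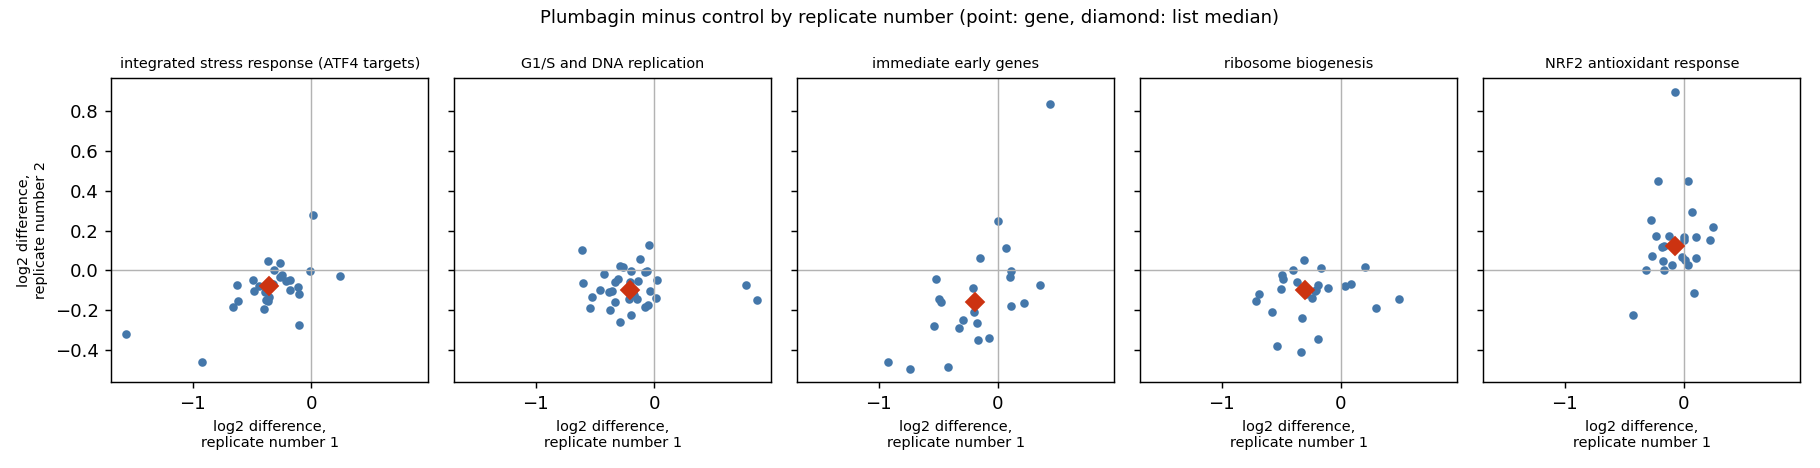
Log2 difference between plumbagin and control in the arrays with number 1 (x axis) and number 2 (y axis) for the 4 lists that fell and the NRF2 antioxidant list. Each point is a gene and the diamond is the list's median; the 4 medians lie below 0 on both axes, and the NRF2 median lies at -0.07 and 0.12.

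The NRF2 antioxidant list was examined because plumbagin is a redox-cycling quinone. Of its 25 measured members, 14 were higher and 11 lower, with a median of 0.03 and a camera adjusted p of 0.413. The members with the smallest p were Mafg, a small Maf partner of NRF2 (-0.32 ± 0.11, log2, SE), Blvrb, a biliverdin reductase (0.24 ± 0.08), Nqo1, a quinone reductase with means below the background level (0.18 ± 0.12), and Slc7a11, the cystine transporter subunit (-0.16 ± 0.11, and -0.08 with its probe sets averaged or after cyclic loess). None passed over all genes or adjusted over the list alone (0 and 0). Between plumbagin 2 and control 2, 23 of the 25 members were higher, with a median of 0.12 at percentile 100 of the brightness-matched lists. Between plumbagin 1 and control 1, 10 were higher, with a median of -0.07 at percentile 69.9. The change of the list's median from number 1 to number 2 lay at percentile 96.3 of the matched lists, inside the central 95%, so the arrays did not separate the response in number 1 from that in number 2. Hmox1, heme oxygenase 1, chosen after its values were seen, had log2 values of 6.73 and 7.28 in controls 1 and 2 and of 6.66 and 8.18 in plumbagin 1 and 2. Without control 1 the list was called higher (median 0.12, camera adjusted p = 0.000270), while its median was -0.12 without control 2 (adjusted p = 0.344), -0.02 without plumbagin 1 (0.321) and 0.04 without plumbagin 2 (0.790).

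The melanocyte pigmentation list was lower in 18 of 24 members, with a median of -0.06 and a camera adjusted p of 0.505. Its 4 members with the smallest p were Trpm1 (-0.24 ± 0.10, log2, SE), Rab32 (-0.32 ± 0.14), Mlph (-0.25 ± 0.16, and -0.14 with its probe sets averaged) and Atp7a (0.22 ± 0.16). The abundant melanin enzyme genes Tyr, Tyrp1 and Dct differed by -0.05 ± 0.14, -0.01 ± 0.08 and -0.01 ± 0.09, the melanosome matrix gene Pmel by -0.06 ± 0.10, and the lineage transcription factor gene Mitf by 0.04 ± 0.29. The 95% intervals of these 5 genes, chosen for their known role and not by their p, reached from -0.75 to 0.83 for Mitf and from -0.23 to 0.21 for Tyrp1. The signs of Tyrp1 and Dct turned with repeated quantile normalization (0.01 and 0.01), and that of Mitf turned when its probe sets were averaged (-0.05). With 1 array left out, Mitf differed by -0.30 without plumbagin 2 and -0.20 without control 1, while Tyr (0.11), Tyrp1 (0.03), Dct (0.06) and Pmel (0.03) were above 0 without plumbagin 1, and Tyr (0.01), Tyrp1 (0.02) and Dct (0.03) without control 2. Without plumbagin 2 the list was called lower (median -0.16, camera adjusted p = 0.0375), while its median was 0.06 without plumbagin 1 (adjusted p = 0.101) and 0.00485 without control 2 (0.920).

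Of the other 18 pathway lists none was called, and the smallest camera adjusted p was 0.0776, shared by STAT3 targets (median -0.10), autophagy and lysosome genes (-0.08) and hypoxia response genes (0.05). The hypoxia list was called higher when dim genes were filtered out (median 0.12, adjusted p = 0.00258 and 0.00267 with the 2 filters) and when every probe set was tested on its own (median 0.06, adjusted p = 0.0303). With 1 array left out, autophagy and lysosome genes were called lower without control 1 (median -0.08, adjusted p = 0.00946) and without plumbagin 2 (-0.23, 0.000352), and proteasome genes were called lower without control 2 (-0.20, 0.00180) and without plumbagin 1 (-0.12, 0.00400). Heat shock genes were called higher without plumbagin 2 (0.14, 0.0367), cholesterol synthesis genes (0.09, 0.0380) and pentose phosphate genes (0.20, 0.0452) higher without control 1, and G2/M genes lower without plumbagin 1 (-0.18, 0.0163). With other arrays left out the same lists had medians of the opposite sign and no call: 0.03 without plumbagin 1 for autophagy and lysosome genes, 0.03 without control 1 and 0.01 without plumbagin 2 for proteasome genes, -0.11 without plumbagin 1 for heat shock genes, -0.05 without control 2 for cholesterol synthesis genes, -0.21 without control 2 for pentose phosphate genes and 0.11 without plumbagin 2 for G2/M genes. The p53 targets (median -0.05, adjusted p = 0.757), apoptosis regulators (-0.04, 0.884), NF-kB targets (-0.01, 0.972), interferon response genes (0.02, 0.246) and matrix, adhesion and invasion genes (-0.01, 0.439) were not called. Heat shock genes (0.05, 0.370), ER chaperones (0.01, 0.370), cholesterol synthesis genes (0.04, 0.370), glycolysis genes (-0.02, 0.681), oxidative phosphorylation genes (-0.04, 0.364), proteasome genes (-0.06, 0.123), pentose phosphate genes (-0.02, 0.681) and replication-dependent histones (-0.14, 0.617) were not called either. G2/M and mitosis genes (median -0.05, adjusted p = 0.878) and DNA damage repair genes (-0.05, 0.759) had a camera direction above 0, opposite to their medians, as did the matrix list. The pentose phosphate list had a mean of 0.000371, opposite in sign to its median and camera direction. Metallothionein and metal response genes had too few measured members for a test, and Mt1 differed by 0.10 ± 0.12, Slc30a1 by -0.11 ± 0.27 and Slc39a10 by 0.29 ± 0.19. The sign of Slc30a1 turned with probe sets averaged (0.04), without control 2 (0.01) and without plumbagin 1 (0.25), and that of Mt1 without control 2 (-0.02).

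Among single genes, those with the smallest p in each direction were taken, 12 higher and 12 lower, and none of the 24 passed the test (limma adjusted p = 1 for each). The higher genes differed by 0.25 to 0.52. They included Zfp950 (0.52 ± 0.15, log2, SE), Epas1, which encodes the hypoxia-inducible factor HIF-2α and had a control mean of 4.90, below the background level (0.44 ± 0.12), Dagla, a diacylglycerol lipase (0.38 ± 0.11), Mgst1, a microsomal glutathione transferase (0.30 ± 0.08), and Kcnq1ot1, an imprinted long noncoding RNA (0.35 ± 0.11). The others were Fam241a, Mib1, Megf9, Cdkl2, Plxna4, Zfp354c and Sgk3. The lower genes differed by -0.31 to -0.46. Beside Polr1a and Nop16 they included Farsa, the phenylalanyl-tRNA synthetase alpha subunit (-0.46 ± 0.12), Sgf29, a chromatin reader of the SAGA complex (-0.41 ± 0.08), Tfpt (-0.40 ± 0.09), Ppp1r11 (-0.38 ± 0.10), and Hps1, a gene of lysosome-related organelle biogenesis (-0.34 ± 0.09). The others were Mmachc, Dus2, Fkbp8, Tnfaip1 and Uxs1. The 24 genes had 15 other probe sets above background, of which 2, for Sgk3 and Farsa, had the opposite sign. With all probe sets of a gene averaged, 14 of the 24 differences shrank by over 1.5 times, with the sign kept, among them Epas1 (0.22), Mgst1 (0.15), Polr1a (-0.30), Tfpt (-0.15), Cdkl2 (0.11) and Farsa (-0.12).

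**Figure D2:**
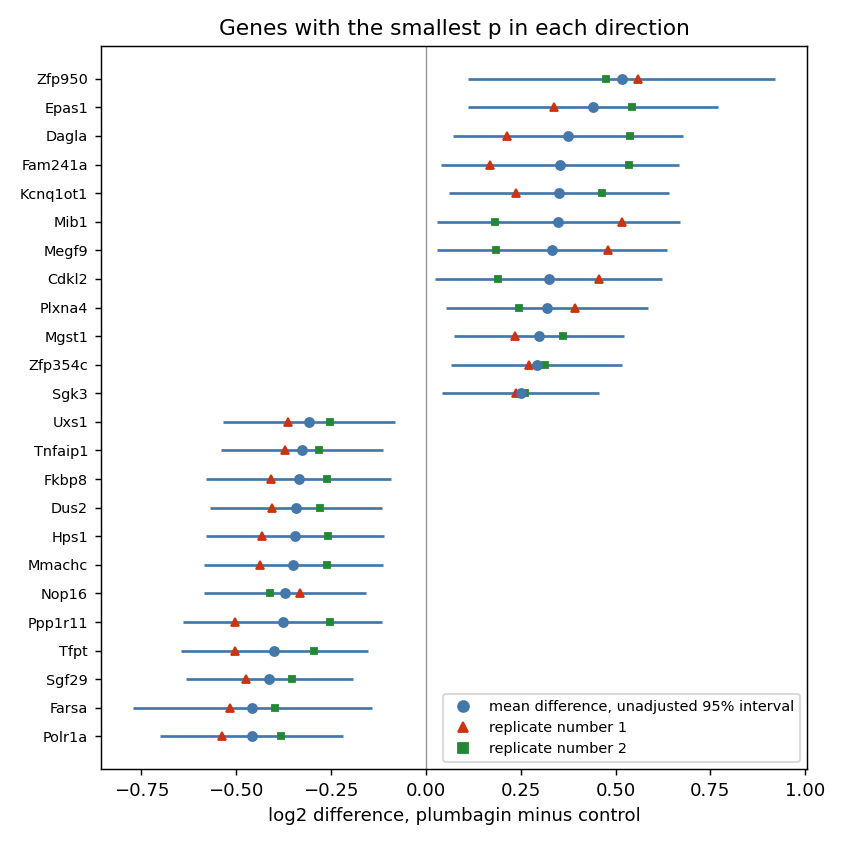
Log2 difference between plumbagin and control for the 12 genes with the smallest p in each direction. Circles are mean differences with unadjusted 95% intervals (limma), triangles the arrays with number 1 and squares those with number 2; the genes were chosen by p, and none passed after adjustment.

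Over all 17097 genes limma called 0 at an adjusted p of 0.05 (smallest adjusted p = 1), and 169 were at an unadjusted p under 0.05, 44 higher and 125 lower, where 854.85 would be reached by chance. With cyclic loess normalization, added after seeing the data, the split was 99 higher and 107 lower. An eBayes trend, fixed before and run on the same values, gave 105 higher and 101 lower. The split stayed uneven with robust eBayes (43 and 121) and with repeated quantile normalization (64 and 150). No gene differed by 2-fold or more in its mean, and the largest difference was -0.98 ± 1.36 for the histone gene H1f4. Both plumbagin arrays lay above both control arrays for 1744 genes and below them for 2597, together 25.4% of genes against 33.3% by chance. The median SE was 0.10 and the median half-width of the 95% interval 0.28, and the interval lay within 2-fold for 96.3% of genes. In simulations of this comparison on 17097 genes, limma called 0.2% of genes moved by 0.5 on the log2 scale, 42.7% of those moved by 1 and 89.5% of those moved by 2. These simulated genes varied independently and with no difference between the numbers, so the shares may not hold for these arrays.

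Arrays with the same number lay closer together than arrays of the same treatment. The SD over genes of the log2 difference was 0.11 between plumbagin 2 and control 2 and 0.23 between plumbagin 1 and control 1, against 0.27 between the controls and 0.26 between the plumbagin arrays. Genes that differed by 2-fold or more numbered 1 and 39 between arrays of the same number, 159 between the controls and 94 between the plumbagin arrays. The 1 gene between plumbagin 2 and control 2 was Ddx6, an RNA helicase gene (-1.32), with 0.11 between plumbagin 1 and control 1. Across genes, which are not independent replicates, the differences within number 1 and within number 2 correlated with r = 0.04, and with r = 0.09 among genes above background.

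**Figure D3:**
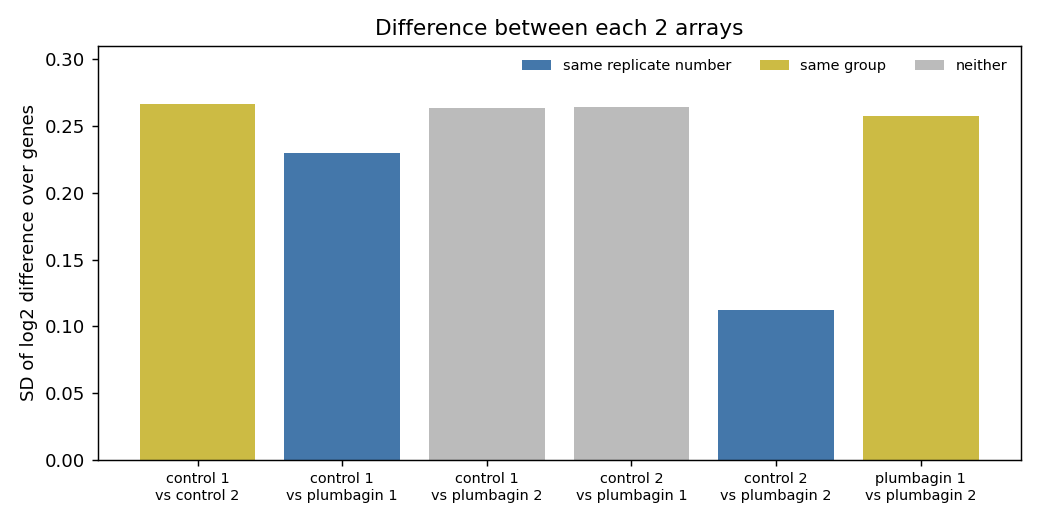
SD over 17097 genes of the log2 difference between each 2 of the 4 arrays, as bars from 0. The bar for control 2 against plumbagin 2 is the lowest at 0.11, and the next lowest, control 1 against plumbagin 1, is at 0.23.

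RNA integrity measures and markers of other cell types were compared between the arrays. The 3-prime minus 5-prime difference of the Actb control probe sets was 0.47 and 0.50 in controls 1 and 2 and 0.56 and 0.52 in plumbagin 1 and 2, and that of Gapdh lay between -0.03 and 0.01. Macrophage, lymphocyte, fibroblast, endothelial and keratinocyte marker lists had medians of 0.00, 0.00, 0.00, 0.00 and 0.06, and none was called (smallest camera adjusted p = 0.782). Few of these markers were above the background level, 2 of 13, 1 of 10, 1 of 12, 2 of 10 and 0 of 11, so a median near 0 carries no information on a change in the others. Erythroid markers had too few measured members for a test, and Hba-a1, Alas2 and Slc4a1 differed by 0.03 ± 0.09, -0.07 ± 0.10 and -0.10 ± 0.13 (log2, SE). Each of these signs turned when an array was left out, to -0.05 for Hba-a1 without plumbagin 1, and to 0.02 for Alas2 and 0.03 for Slc4a1 without plumbagin 2.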

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

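The hybridization spike-in controls, which are added to the labelled sample and lie outside the comparison of genes, were brighter on the plumbagin 1 array than on the others. Their mean log2 value over 9 probe sets was 9.79, which was 0.75 above the higher of the controls. The means were 8.73 and 9.04 on controls 1 and 2 and 8.96 on plumbagin 2, and all 9 probe sets were brighter on plumbagin 1 than on both controls. The poly-A spike-in controls, added to the RNA before labelling, had means of 12.61, 12.71, 12.76 and 12.69 on control 1, control 2, plumbagin 1 and plumbagin 2. The difference was not tested and no explanation was weighed for it.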

How the results depend on the processing

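Of the settings here cyclic loess was chosen after seeing the data. The count of genes past the threshold was 0 with every alternative run. The count of lists depended on the test: 4 with camera's preset correlation, 0 with an estimated one (smallest adjusted p = 0.875), 0 with fry. At an unadjusted fry p under 0.05 were 2 lists, p53 targets (0.00997), not called by camera, and immediate early genes (0.0186). For ribosome biogenesis, ATF4 targets and G1/S genes the unadjusted fry p was 0.116, 0.322 and 0.707. The preset correlation takes the genes of a list as nearly independent. The estimates of 0.72 for G1/S genes and 0.45 for ATF4 targets argue against that for these lists, as far as 4 arrays can estimate it. Their p with the preset correlation is then too small. The estimated version also leaves few degrees of freedom with 4 arrays. For ribosome biogenesis (0.13) and immediate early genes (-0.04) the loss of the calls therefore cannot show that they came from correlation. Leaving out each array in turn gave 4 to 7 lists, with 7 without control 1. Ribosome biogenesis was called lower with each alternative of normalization, filter, probe set, block and left-out array, with medians of -0.11 to -0.25 when an array was left out. The trend and robust variance models do not enter camera, so no list call could change under them. Camera directions turned when 1 array was left out: for pentose phosphate genes without control 1 (median 0.20, adjusted p = 0.0452, range -0.21 to 0.20), for G1/S genes without control 1 (0.10) and without plumbagin 2 (0.05, range -0.42 to 0.10), and for G2/M genes without plumbagin 1 (-0.18, adjusted p = 0.0163, range -0.20 to 0.11). The cause was not tested. Genes with a 2-fold mean difference numbered 0, 2 with every probe set on its own, and 4 to 58 when an array was left out (58 without control 2). Of 336 list values under alternatives, 8 lost a call, 12 gained it and 4 turned with a call on either side; the camera direction differed in 44, these 4 included. The 336 include the values under the trend and robust variance models, which could not differ from the main ones.

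With the replicate number as a block, 0 genes passed (smallest adjusted p = 0.919, with 434 at an unadjusted p under 0.05) and 5 lists were called, autophagy and lysosome genes in addition to the 4. Deviations of same-numbered arrays from their group means correlated at 0.54 across genes, but with 2 numbers the arrays share only a number in the labels. Weak signals limit the comparison: the 8460 genes at or below the background level carry little information on a change.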

Other observations

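In this part, the comparison of the numbers was chosen after the result was seen. So were all tests of an explanation but that of a brightness-dependent shift in the antioxidant list. The fit of treatment, averaging of probe sets and leaving out of arrays were fixed before. Arrays with number 2 differed from arrays with number 1 more than plumbagin from control. In limma, with treatment as a covariate, number 2 against number 1 gave 0 genes past an adjusted p of 0.05 (smallest 0.167). At an unadjusted p under 0.05 there were 2698 genes, against 434 for plumbagin with the number as a block. A difference of 2-fold or more was reached by 77 genes, 71 higher and 6 lower in number 2. Txnip, a thioredoxin-binding protein induced by glucose, was among the lower (-2.95 ± 0.12, log2, SE), as were H1f4 (-2.81 ± 0.15) and the cell cycle inhibitor Cdkn1a (-1.01 ± 0.09). Nupr1, a stress-induced chromatin protein (1.34 ± 0.10), and Lcp1, an actin-bundling protein (1.59 ± 0.08), were among the higher. Camera called 13 of the 24 lists, 8 lower and 5 higher in number 2; G1/S genes had a median of -0.41, G2/M genes of -0.28 and ATF4 targets of 0.14. With an estimated correlation 0 lists were called (smallest adjusted p = 0.737).

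Tiparp, a target of the aryl hydrocarbon receptor, had a difference of 0.60 ± 0.22 between plumbagin and control, with 0.61 in the arrays with number 1 and 0.58 in those with number 2 (limma adjusted p = 1). Cyp1a1 and Cyp1b1, targets of the same receptor, differed by 0.04 ± 0.08 and 0.07 ± 0.09, at mean log2 values of 3.25 and 3.67, below the background level; Cyp1b1 was at -0.03 with its probe sets averaged. These genes were chosen after the values were seen, and no list of such targets was tested.

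Same-numbered arrays lay closest together, with SDs of 0.11 and 0.23 against 0.26 or more between the other arrays. A culture, labelling or hybridization batch per number stays open, and the labels give none. The hybridization spike-in means differed by 1.06 within number 1, against 0.24 or more between arrays of different number. Within number 2 they lay closer, at 9.04 on control 2 and 8.96 on plumbagin 2, so the numbers go opposite ways. These controls are added to the labelled sample, so they cannot bear on a culture or labelling batch. A deviation of plumbagin 1 alone is argued against by the SD between the controls, which was 2.37 times that between plumbagin 2 and control 2. A plumbagin 2 array holding the RNA of control 2 is argued against by 9 of 24 list medians outside the central 95% of matched lists. For lists of unrelated genes 1.2 are expected, but lists share co-regulated genes, so this argument is weak. An untreated second culture stays open.

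The fall of the ribosome biogenesis, ATF4 target and immediate early lists is not wholly a brightness-dependent shift. After cyclic loess the median of their medians kept 75.3% of its size, with 65.2% to 89.6% per list, and camera called all 3 with the preset correlation. They were grouped apart from G1/S genes, whose call ended after loess, so the 3 calls are no separate support. Before loess these calls were lost with an estimated correlation (adjusted p = 0.875 each). For G1/S genes the median went from -0.14 to -0.09 and the call ended (adjusted p = 0.0538), but such a shift as the whole cause is argued against by the list's percentiles among brightness-matched lists after loess, 0.96 in number 1 and 0 in number 2. Co-regulation of genes within a list without an effect of plumbagin stays open, since 5 of the 8 lists that departed in number 1 departed on the same side in number 2, neither few nor all. An effect of plumbagin stays open beside it.

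The antioxidant list was higher in plumbagin 2 than in control 2, with Hmox1 at 0.89, Srxn1 at 0.45 and Cbr3 at 0.45, and at -0.07, 0.04 and -0.22 in number 1. With treatment compared over the remaining arrays, Hmox1 was at -0.35 without plumbagin 2, and Srxn1 and Cbr3 were at -0.18 and -0.32 without control 2; averaging probe sets took Srxn1 from 0.24 to 0.11. Loess turned the list's number 1 median from -0.07 to 0.05 and raised its percentile from 69.9 to 86.2, so brightness accounts for part of the gap, but a shift that hid a departure in number 1 is argued against, as the percentile stayed inside the central 95%. A higher baseline in control 1 stays open: the list was 0.16 higher in control 1 than in control 2, at percentile 97.51, which lay on the limit within the 0.31 margin of the random draws. The difference between the numbers itself did not leave the central 95% (percentile 96.3), and an effect of plumbagin in both stays open.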
